A study of Mus musculus with 8 samples.

How the data were processed

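Kidneys were taken from mice of 3 genotypes, namely wild type, Col4a3-/- (single mutant) and Col4a3-/-OPN-/- (double mutant), and total RNA of each kidney was hybridized to 1 array. The labels name an RNA kit and a labelling kit that are commonly used for small RNAs. The probe sets in the file are those of a whole-transcript mouse gene array, and most name protein-coding genes, so the comparisons were made on genes. The deposited values are log2 expression values, 1 per probe set and array, with a range from 4.20 to 13.43. The unit was read from that range, which fits a log2 scale on a 16-bit scanner. The authors' normalization and summarization are not given in the sources used here. Array medians were close, and the values were used as deposited.

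The table held 33793 probe sets. Of these 23521 named 1 gene, 1814 named several and 8458 named none. For a gene with several probe sets, which was the case for 1082 of 22180 genes, the probe set with the highest mean was kept. Genes with a mean over the 8 arrays above the 75th percentile of all probe sets, a log2 value of 6.64, were tested, and 7145 passed this filter. Gene positions are from the RefSeq annotation of the mouse assembly GRCm38. The osteopontin gene is not reported here, and the second deletion was not checked. No fixed background level was used, and the number of arrays limits the precision.

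The comparisons, the tests, the rule for naming genes and most of the other settings tried were fixed before the data were examined. They had been written for microRNAs, because of the labelling kit, and the fallback filter of that plan (the 75th percentile) was used for genes. The 16 planned microRNA lists were not tested, since the array holds 472 genes of microRNA precursors, of which 26 passed the filter, and no mature microRNAs. In their place 36 gene lists of cell types, pathways and injury responses, with 613 entries of which 562 were measured, were written after the probe names were read and before any difference between groups was computed. The 27 lists with at least 3 tested members were tested.

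Groups were compared in 1 linear model of the 3 groups with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 5 residual degrees of freedom. P values were two-sided, were adjusted by Benjamini-Hochberg over all tested genes of a comparison, and were called under 0.05. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, and were adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. List means per array were compared between the mutants by an exact permutation test. Genes are named by the rule fixed in advance, which takes up to 12 higher and 12 lower genes by size among those called. Where fewer than 10 were called, it adds those with the smallest p up to 10. Members of the lists may be named besides these. The overlap of comparisons that share a group was set beside 100 simulations of unchanged groups.

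Sex was read from Xist and the Y-linked genes Uty, Kdm5d and Eif2s3y. Because all wild type mice were read as male, a second fit with a term for sex and 4 residual degrees of freedom was added after the sexes had been seen. It takes the effect of sex as equal in all groups and estimates it from the mutants. The same rules were applied to it. Differences among the 4 male arrays and among the 4 female arrays were computed as well.

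The other settings fixed in advance were no filter, quantile normalization, median centring, cyclic loess, an intensity trend with a robust prior, array weights, a fit of only the 2 groups compared, the replicate number as a block, a minimum log2 difference of 1 and leaving out each array in turn. Added after the data were seen were the sex term, males or females alone, a filter at the 50th percentile, a filter on 2 or more arrays, a floor at the 50th percentile and the inclusion of unnamed and several-gene probe sets. The fit was tested on simulated data with 200 changed genes of known size among 7145. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.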

Results

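Gene expression was measured in whole kidneys of 8 mice aged 2 months, with 1 array per mouse. The 2 wild type mice were compared with 3 mice that lack Col4a3 and with 3 mice that lack both Col4a3 and osteopontin. Col4a3 encodes a chain of the type IV collagen network of the glomerular basement membrane, and its loss models Alport syndrome, a hereditary kidney disease. Osteopontin is a secreted matrix protein and cytokine made by injured tubule cells. The groups are called wild type, single mutant and double mutant. All values are on a log2 scale, the median over all probe sets lay between 5.18 and 5.25 on the 8 arrays, and the number of arrays limits the precision.

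The groups differed in the sex of the mice, which was read from the arrays because the labels used here do not give it. Xist, the RNA that silences an X chromosome in females, measured 10.02 and 8.93 in single mutants 1 and 3. It measured 9.59 and 8.85 in double mutants 1 and 2, and between 4.52 and 4.64 on the other 4 arrays. The Y-linked genes Uty, Kdm5d and Eif2s3y were high on exactly those other 4 arrays. Eif2s3y measured 7.81 and 8.06 in wild type, 7.83 in single mutant 2 and 7.69 in double mutant 3, and at most 4.56 elsewhere. Both wild type mice were therefore read as male, as was 1 of 3 mice in each mutant group. Every comparison is given as planned and again from a fit with a term for sex, which was added after this was seen.

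**Figure D1:**
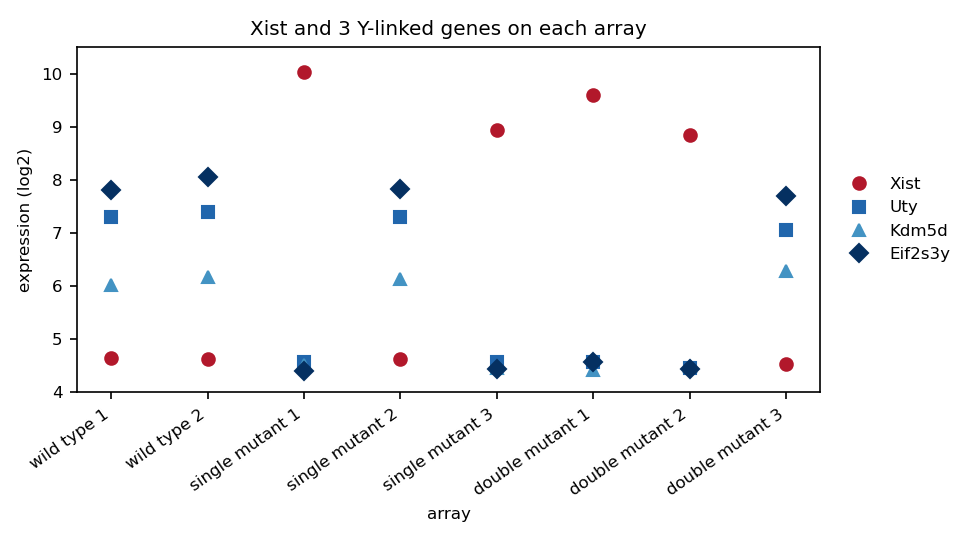
Expression (log2) of Xist and of the Y-linked genes Uty, Kdm5d and Eif2s3y on each of the 8 arrays, 1 point per gene and array. The 4 arrays with Xist above 8.8 have all 3 Y-linked genes below 4.6.

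The targeted gene itself was lower in both mutants without passing the test. Col4a3 (chromosome 1, 82586921 to 82722059, GRCm38) had a mean of 8.60 ± 0.25 (SD, n = 2) in wild type. It had a mean of 7.31 ± 0.61 (SD, n = 3) in single and 6.85 ± 0.74 (SD, n = 3) in double mutants. The single mutant differed from wild type by -1.29 (SE 0.46, adjusted p = 0.162 in limma) and the double mutant by -1.75 (SE 0.46, adjusted p = 0.0998). With the sex term these differences were -0.73 (adjusted p = 0.201) and -1.19 (adjusted p = 0.0657). Whether the probes lie within the deleted sequence is not given in the sources used here. The partner chains Col4a4 and Col4a5 differed from wild type by 0.03 and 0.21 in the single mutant, and neither passed. The osteopontin gene was not analysed here, so the second deletion of the double mutant was not checked on its own gene.

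The single mutant was compared with wild type to describe the Alport kidney. Its kidneys had more transcript of Nupr1, a stress-induced regulator of transcription, and less of Msrb1, which repairs oxidized methionine. Genes of fibrillar collagen and matrix, macrophages and injured tubules were higher as groups, by medians of about 1 or more on the log2 scale. Genes of proximal tubule transport and mitochondrial respiration were lower as groups, by a median of -0.59 and -0.47. These calls of groups were made by camera at its preset correlation, and none held with an estimated correlation or by fry. Single mutant 2, the group's 1 male, contributed much of them, and without it the proximal tubule genes no longer passed.

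Nupr1 (chromosome 7, 126623246 to 126625470) was 3.27-fold higher in the single mutant, with a mean of 8.52 ± 0.06 (SD, n = 3) against 6.81 ± 0.04 (SD, n = 2) in wild type. Its difference was 1.71 (SE 0.14, adjusted p = 0.0065). Msrb1 (chromosome 17, 24736593 to 24742778) was 2.89-fold lower, with a difference of -1.53 (SE 0.12, adjusted p = 0.0065). These were the only genes past the threshold, 1 higher and 1 lower of 7145 tested with limma, while 1656 had an unadjusted p under 0.05 and chance gives 357. Without either wild type array, or without single mutant 1 or 3, neither gene passed, while 3 genes passed without single mutant 2 and 4 without double mutant 3. The genes with the next smallest p did not pass. They were lower for Nat8 at -2.06, Treh, the brush-border trehalase, at -1.88, Lap3 at -1.36, Ephx2, an epoxide hydrolase, at -1.35, Agtrap at -1.13 and Dnajc22 at -1.01. They were higher for Lcn2, an iron-carrier protein of injured tubules, at 2.87 and for Map3k1 at 1.21.

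By camera, 10 of 27 gene lists were higher and 5 were lower in the single mutant. With an estimated correlation none passed, and the smallest adjusted p was 0.502. None passed by fry either. The fibrillar collagen and matrix list had a median of 1.23, with 22 of 23 members above wild type. No member passed over all genes, and 18 were higher when adjusted over the list alone. Macrophage and monocyte genes had a median of 1.30, with 12 of 12 members above wild type and 9 higher when adjusted over the list alone. Tubule injury genes had a median of 0.98, with 10 of 19 higher and 1 lower when adjusted over the list alone. The median was 0.95 for fibroblast, pericyte and smooth muscle genes, 0.94 for MHC class II, 0.70 for cytokines and chemokines and 0.58 for basement membrane genes. It was 0.60 for receptors of osteopontin, with 2 of 4 members higher when adjusted over the list alone, 0.40 for the interferon response and 0.33 for podocyte genes. Among the lower lists, proximal tubule transporters and markers had 1 of 30 members above wild type and 4 lower when adjusted over the list alone. Oxidative phosphorylation genes had 0 of 24 members above wild type and 1 lower when adjusted over the list alone. Fatty acid oxidation and peroxisome genes and cholesterol synthesis genes each had a median of -0.39. Male-high kidney genes, whose transcripts are known to be more abundant in male mice, had the lowest median at -3.28.

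These list values rested in part on single mutant 2, whose values correlated at 0.865 and 0.839 with the other single mutants, which correlated at 0.959 with each other. It correlated at 0.948 with double mutant 3, the other male mutant. Without single mutant 2 the mean difference from wild type went from 1.33 to 0.85 for macrophage genes, from 1.30 to 0.84 for matrix and from 0.97 to 0.63 for tubule injury. It went from -0.70 to -0.30 for proximal tubule, from -0.46 to -0.24 for oxidative phosphorylation, from -0.50 to -0.26 for cholesterol synthesis and from -0.35 to -0.02 for fatty acid oxidation genes. Camera then called 10 lists higher and 2 lower, the latter being oxidative phosphorylation and male-high kidney genes.

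The other 12 lists did not pass in this comparison. Their medians were 0.66 for complement, 0.25 for endothelium, 0.21 for lipid uptake, storage and efflux, 0.12 for immediate early genes, 0.04 for endoplasmic reticulum stress and 0.0049 for the circadian clock. They were -0.38 for NRF2 targets, -0.24 for mitochondrial dynamics and biogenesis, -0.15 for glycolysis and gluconeogenesis, -0.15 for renin-angiotensin and blood pressure genes and -0.05 for collecting duct genes. Loop of Henle and distal tubule genes had a median of 0.05 and a mean of -0.06. Another 9 lists had fewer than 3 members above the filter and were not tested, namely adrenal gland, blood erythroid, cell cycle, fat, liver, neutrophil, skeletal muscle, T, B and NK cell and Y-linked genes. Over all their measured members, their medians for the single mutant against wild type lay between -1.87 for Y-linked genes and 0.24 for the cell cycle.

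**Figure D2:**
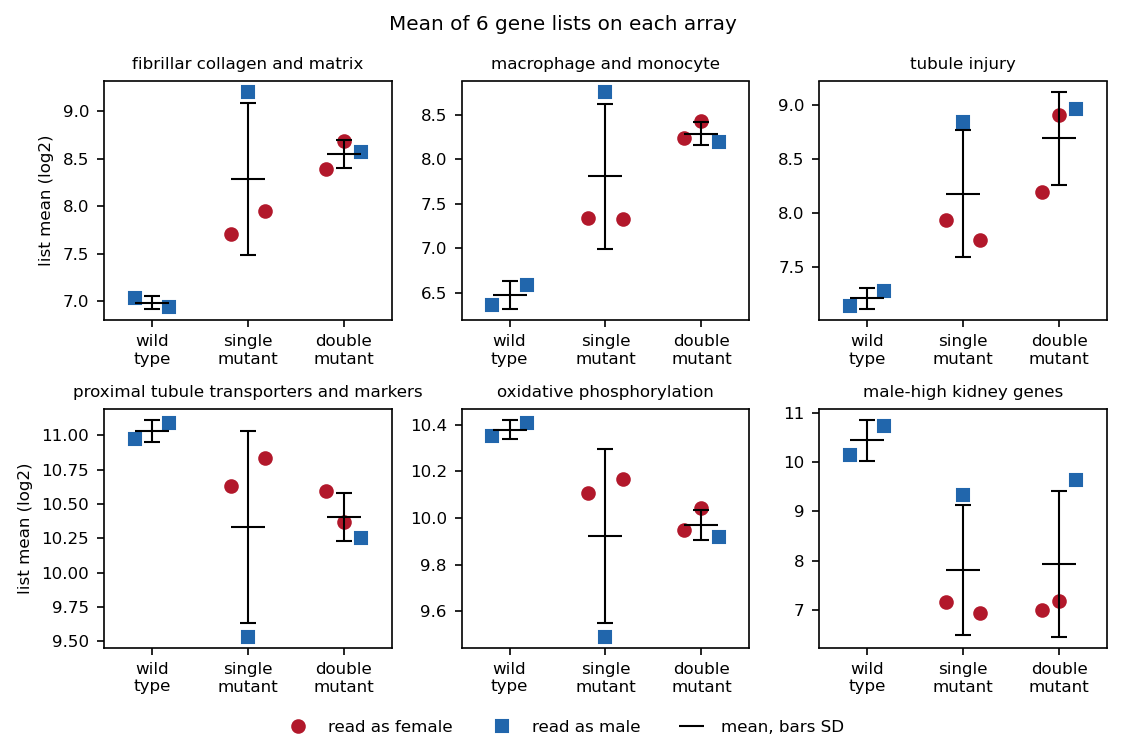
Mean log2 expression of 6 gene lists on each array by group, with the point shape and colour giving the sex read from the array, a dash for the group mean and bars for the SD. Male-high kidney genes lay between 6.95 and 7.17 in the 4 female mutants, at 9.33 and 9.63 in the 2 male mutants and at 10.15 and 10.73 in wild type.

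With the term for sex, far more genes separated the single mutant from wild type. Col1a1 and Col3a1, the main chains of fibrillar collagen, Tnc, a matrix protein of wounds, Lyz2 and Ctss, markers of macrophages, and the T cell attractant Ccl5 were all higher. Dnase1, Slc22a22, an organic anion carrier, and Acot2, a mitochondrial thioesterase, were lower. In limma 522 genes were higher and 1424 lower, and 3092 had an unadjusted p under 0.05. The median of all genes was itself shifted by -0.15 in this fit, against -0.03 after median centring and -0.0015 after cyclic loess. The list medians of this fit are therefore given relative to that shift. Cyclic loess called 922 higher and 922 lower genes, and median centring called 794 higher and 1008 lower. These counts rest on single mutant 2, the group's 1 male, since without it 0 genes passed and 1825 had an unadjusted p under 0.05. Without wild type 2 they came to 25 and 41, and without wild type 1 to 256 and 904.

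The 12 largest increases among the genes called with the sex term were led by Gm3893 at 4.18. Col1a1 was higher by 3.93 (SE 0.68, adjusted p = 0.0106), a 15.3-fold difference, Lyz2 by 3.68, Col3a1 by 3.68, the small nucleolar RNA Rnu3a by 3.50 and Lcn2 by 3.42 (SE 0.28, adjusted p = 0.0053). Ccl5 was higher by 3.27, Tnc by 3.17, Mgp, an inhibitor of calcification, by 2.96, Serpina3n, an acute-phase protease inhibitor, by 2.92, the adhesion molecule Vcam1 by 2.84 and Ctss by 2.82. The largest decreases among called genes were in Dnase1 at -3.30 and the kallikrein Klk1b22 at -3.15. They went on with Akr1c21 at -2.80, Acot2 at -2.79, Cyp2d26 at -2.79, Slc22a22 at -2.77, Slco4c1 at -2.71 and Rdh16f2 at -2.68. Hpd was lower by -2.48, Slc22a19 by -2.47, Cndp1 by -2.42 and Shmt2, a mitochondrial enzyme of serine metabolism, by -2.40. None of these increases or decreases passed without the sex term, which subtracts an effect of sex estimated in the mutants. Hpd, Rdh16f2, Cyp2d26 and Slc22a19 were higher in females by 3.36, 3.46, 3.27 and 2.57, and without the sex term they differed from wild type by -0.24, -0.37, -0.61 and -0.75 without passing. Among males alone, where the group is 1 mouse, Hpd differed by -3.34 and Slc22a19 by -2.71. In the males alone, the 1 single mutant exceeded the 2 wild type mice by 4.77 in Col1a1 and 4.29 in Lyz2 and was lower by -4.20 in Dnase1.

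With the sex term, camera called 9 lists higher and 8 lower, and without single mutant 2 it called 6 and 2. With an estimated correlation none passed, and the smallest adjusted p was 0.398. Fry called 17. Of 23 fibrillar collagen and matrix genes 16 were higher over all genes and 21 when adjusted over the list alone, with a median 1.75 above the shift. Of 12 macrophage and monocyte genes 10 were higher over all genes and 10 when adjusted over the list alone, with a median 1.81 above the shift. The fit takes the effect of sex as equal in both mutants. Macrophage means were 7.34 and 7.33 in female single mutants and 8.75 in the male. In double mutants they were 8.24 and 8.43 in females and 8.19 in the male. As fitted, the list median against wild type was 1.67 in single and 2.21 in double mutants. Males alone, with 1 mouse per mutant, gave 2.24 and 1.68, so the order of the mutants rests on that assumption. Of 19 tubule injury genes 10 were higher over all genes, while 14 were higher and 1 lower when adjusted over the list alone. Krt18, a keratin of stressed epithelium, was higher by 1.55 and the calcium-binding S100a6 by 2.47. Havcr1, the injury marker KIM-1, was higher by 3.14 without passing, with a wild type SD of 2.22. Basement membrane genes had 7 of 15 members higher and 8 when adjusted over the list alone, with Col4a1 at 1.60 and Col4a2 at 1.53, chains of the collagen found in most basement membranes. Of the receptors of osteopontin, the integrin chains Itga9 at 1.03, Itgav at 0.78 and Itgb1 at 0.66 were higher and Itgb5 did not pass.

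Among the lower lists of that fit, 17 of 30 proximal tubule genes were lower and 22 when adjusted over the list alone, with a median of -0.87 relative to the shift. Examples are the organic anion transporter Slc22a8 at -2.13, Slc13a3, which takes up dicarboxylates, at -1.77 and Slc16a9 at -1.60. Fatty acid oxidation genes had 15 of 25 members lower and 17 when adjusted over the list alone, such as Eci1 at -1.34 and Etfdh at -1.29. Oxidative phosphorylation genes had 12 of 24 members lower and 18 when adjusted over the list alone, such as the respiratory chain subunits Uqcrc2 at -1.08 and Ndufa9 at -1.06. Of 11 NRF2 targets, genes of the antioxidant response, 6 were lower over all genes and 6 when adjusted over the list alone, with Gclm at -1.09 and Nqo1 at -1.24. Collecting duct genes had 4 of 14 members lower, with the water channel Aqp4 at -1.66. Podocyte genes, higher as a list without the sex term, had a median 0.23 above the shift and no member past the threshold, and the list did not pass. As fitted, before the shift is taken off, their median was 0.08 and their mean -0.05. Circadian clock, endoplasmic reticulum stress, endothelium and lipid uptake genes lay at medians of 0.06, 0.02, 0.0080 and 0.09 relative to the shift, and camera also placed them above the other genes without passing. As fitted these medians were -0.09, -0.13, -0.14 and -0.06, and the mean of the lipid list was 0.10.

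The double mutant was compared with the single mutant to ask how an Alport kidney without osteopontin differs from one with it. No single gene separated these groups, and the largest differences by p included Serpina3n, Fgg, a fibrinogen chain, and Cyp27b1, the enzyme that activates vitamin D. As groups, genes of tubule injury, macrophages, the antioxidant response and matrix were slightly higher in the double mutant by camera at its preset correlation, and none of these lists held with an estimated correlation or by fry. The direction of the macrophage and matrix genes was not shared by the sexes, being higher in the female and lower in the male double mutant, a difference that did not pass an interaction test with an estimated correlation.

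In limma 0 genes were higher and 0 lower, with or without the sex term. An unadjusted p under 0.05 was reached by 104 genes as planned and by 273 with the sex term, where chance gives 357. Simulated data of this design had 200 genes changed at once and independent noise. In them 80.5 percent of genes changed by a log2 of 1 were recovered. Differences shared across genes, such as those of sex, were left out, so the percentage may be lower in the real data. Serpina3n had means of 8.32 ± 0.81 (SD, n = 3) and 10.24 ± 0.47 (SD, n = 3), and the difference of 1.92 (SE 0.40) did not pass. Other genes with the smallest p, none of which passed, were Fgg at 2.26, Cyp27b1 at 1.33, Srxn1, an antioxidant enzyme, at 0.57, Cd24a at 0.54, Gadd45b at 0.52 and H6pd at 0.42. On the lower side they were B930095G15Rik at -0.62, Dnm3 at -0.61 and Tbc1d16 at -0.46. In the fit with sex Scpep1 at 0.54, Krt8 at 0.54, Lcn2 at 0.89, Ranbp3l at -0.60 and Atp6v1b1, a subunit of the proton pump of intercalated cells, at -0.59 came next to Serpina3n, again without passing.

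By camera, 8 lists were higher and 0 lower in the double mutant than in the single mutant. With an estimated correlation none passed, and the smallest adjusted p was 0.648. Fry called 0. Of the 10 ways to divide the 6 mutant arrays into 3 and 3, 6 called at least 8 lists by camera, the real division included. Tubule injury genes had a median of 0.44 with 18 of 19 members higher in the double mutant, and macrophage genes had a median of 0.51 with 12 of 12. The tubule injury median was 0.64 in females and 0.02 in males, 1 mouse per mutant, where 10 of 19 members were higher. The median was 0.46 for MHC class II, 0.34 for fibroblast genes, 0.29 for fibrillar collagen and matrix, 0.28 for cytokines and 0.15 for fatty acid oxidation. In males, 1 mouse per mutant, these medians were -0.52, -0.50, -0.72, -0.10 and 0.39, and in females 0.93, 0.85, 0.68, 0.41 and 0.08. NRF2 targets had a median of 0.25 with 11 of 11 members higher, such as Hmox1, the heme-degrading enzyme, at 1.20. No member of these lists passed over all genes, and 1 NRF2 target was higher when adjusted over the list alone. In the fit with sex MHC class II no longer passed (adjusted p = 0.0513), and loop of Henle and distal tubule genes were lower with a median of -0.20 (adjusted p = 0.0286, and adjusted p = 0.584 with an estimated correlation). Endothelium genes had a median of 0.02 and a mean of -0.01.

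The mean of the tubule injury list was 7.93, 8.85 and 7.74 in the single mutants and 8.20, 8.91 and 8.97 in the double mutants (exact permutation p = 0.20, two-sided). The macrophage list had means of 7.34, 8.75 and 7.33 against 8.24, 8.43 and 8.19 (exact permutation p = 0.40). The matrix list had means of 7.71, 9.20 and 7.95 against 8.40, 8.69 and 8.58 (exact permutation p = 0.60). For NRF2 targets the means were 8.85, 8.23 and 8.82 against 9.29, 8.95 and 8.67 (exact permutation p = 0.40). With 3 against 3 mice the smallest p of this test is 0.10. The single male of the single mutant group had the highest macrophage and matrix means of all 8 arrays. In females the median difference of macrophage genes was 1.06 and that of matrix genes 0.68. In males it was -0.61 and -0.72, from 1 mouse each.

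The double mutant was compared with wild type to describe the full difference from a healthy kidney. Of the genes called higher, Serpina3n and Lcn2 increased most, and Nupr1 and Acta2, the actin of smooth muscle and myofibroblasts, were also higher. Msrb1 and Galnt14, which starts the sugar chains of mucin-type glycoproteins, were lower. By camera at its preset correlation the higher groups included macrophages, tubule injury, MHC class II and matrix, as in the single mutant, and none held with an estimated correlation.

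In limma 4 genes were higher and 2 lower than in wild type, and 1544 had an unadjusted p under 0.05. Serpina3n (chromosome 12, 104406646 to 104414334) was higher by 4.47 (SE 0.45, adjusted p = 0.0217) and Lcn2 (chromosome 2, 32384637 to 32387739) by 3.76 (SE 0.39, adjusted p = 0.0217). Nupr1 was higher by 1.98 (SE 0.14, adjusted p = 0.0044) and Acta2 (chromosome 19, 34240336 to 34255585) by 1.34 (SE 0.15, adjusted p = 0.0346). Msrb1 was lower by -1.23 (SE 0.12, adjusted p = 0.0217) and Galnt14 (chromosome 17, 73493207 to 73712138) by -0.97 (SE 0.11, adjusted p = 0.0346). None of the 6 passed without either wild type array or without double mutant 1. The total was 1 without double mutant 2, 3 without single mutant 1 or 3 and 41 without double mutant 3, and without single mutant 2 it came to 292 higher and 298 lower. The next genes by p did not pass, and all 4 were lower, Treh at -1.91, Dnajc22 at -0.96, Fhl1 at -0.95 and Agtrap with a mean of 7.24 against 8.24.

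By camera, 9 lists were higher and 4 lower in the double mutant than in wild type. With an estimated correlation none passed, and the smallest adjusted p was 0.359. Fry called 2, the cytokine list and the fibroblast list. Macrophage genes had a median of 1.82 with 11 of 12 members higher when adjusted over the list alone. Tubule injury genes had a median of 1.41 with 1 of 19 members higher over all genes and 12 when adjusted over the list alone. Fibrillar collagen and matrix genes had a median of 1.39 with 23 of 23 members above wild type and 18 higher when adjusted over the list alone. The median was 1.40 for MHC class II, 1.29 for fibroblast genes, 1.03 for cytokines, 0.67 for receptors of osteopontin, 0.53 for basement membrane and 0.45 for the interferon response. The lower lists were male-high kidney genes at -3.32, proximal tubule at -0.55, oxidative phosphorylation at -0.41 and mitochondrial dynamics at -0.29. NRF2 targets had a median of -0.02 and a mean of 0.02, and renin-angiotensin genes a median of 0.04 and a mean of -0.12.

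With the sex term 457 genes were higher and 1271 lower in the double mutant than in wild type. Here 2976 genes had an unadjusted p under 0.05, and the median of all genes was shifted by -0.15. Cyclic loess, which removed that shift, called 809 higher and 760 lower. Without wild type 2 the counts were 37 and 33, without wild type 1 they were 204 and 666, and without single mutant 2 the lower genes came to 846. The largest increases among called genes were Serpina3n at 4.84 (SE 0.48, adjusted p = 0.0041), Havcr1 at 4.34 (SE 1.25, adjusted p = 0.0419), Lcn2 at 4.31, Col1a1 at 4.23, Lyz2 at 4.12 and Krt20, a keratin of injured tubules, at 4.08. They went on with Gm3893 at 4.07, Col3a1 at 3.97, Ctss at 3.63, Tnc at 3.51, Vcam1 at 3.38 and Fgg at 3.38. The largest decreases among them were Klk1b22 at -5.48, Hpd, of tyrosine breakdown, at -3.12, Cndp1 at -2.92, Dnase1 at -2.86, Rdh16f2 at -2.60 and Slc22a19 at -2.58. Acmsd, Acy1, Slc22a22, Cyp2c23, Cyp51, of cholesterol synthesis, and Slco4c1 were lower by -2.44, -2.38, -2.36, -2.33, -2.32 and -2.31. Of these increases and decreases, only Serpina3n and Lcn2 also passed without the sex term. Here too the sex effect was subtracted, and without it Hpd differed by -0.88, Rdh16f2 by -0.30 and Slc22a19 by -0.87, none of which passed. Cyp2c23 was higher in females by 2.95, so its decrease also rests on the subtracted effect.

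In that fit camera called 9 lists higher and 6 lower. With an estimated correlation none passed, and the smallest adjusted p was 0.29. Fry called 19. Matrix genes had 20 of 23 members higher over all genes and 22 when adjusted over the list alone. Tubule injury genes had 16 of 19 higher by either adjustment, the second being adjusted over the list alone. Macrophage genes had 10 of 12 higher over all genes and 11 when adjusted over the list alone, with Mrc1, a mannose receptor, at 2.62 and Mpeg1 at 2.65. Among males alone, where the group is 1 mouse, the macrophage median was 1.68, below the 2.21 of this fit. Proximal tubule genes had 14 of 30 lower and 1 higher over all genes, and 24 lower and 1 higher when adjusted over the list alone. Fatty acid oxidation genes had 8 of 25 lower over all genes and 15 when adjusted over the list alone, and male-high kidney genes no longer passed (adjusted p = 0.0821). Relative to the shift, circadian clock genes had a median of -0.10 and lipid genes one of 0.07, and camera placed both lists above the other genes without passing. As fitted the lipid list had a median of -0.08 and a mean of 0.16.

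**Figure D3:**
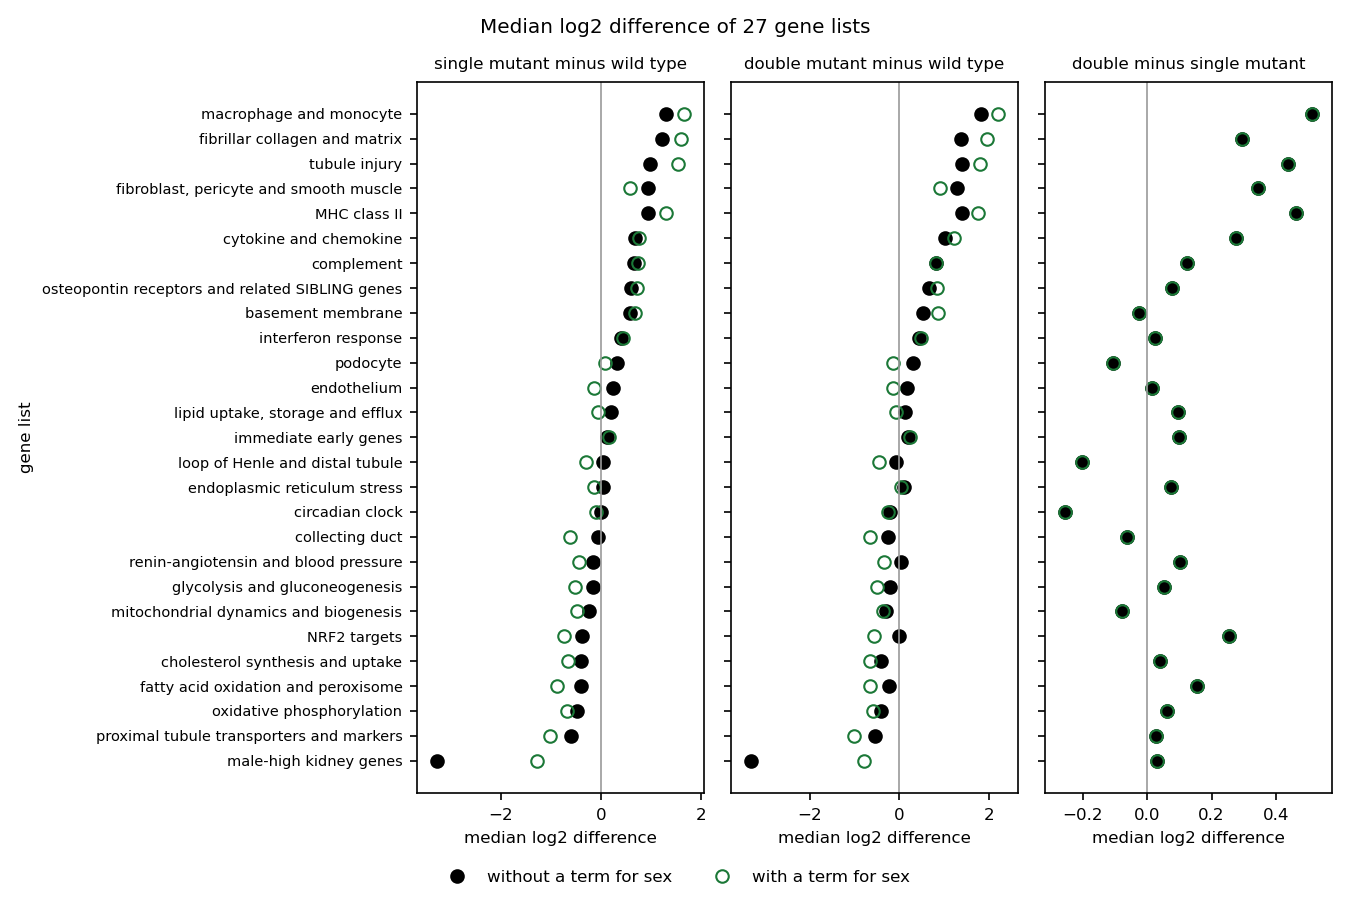
Median log2 difference of each of 27 gene lists in the 3 comparisons, without (filled) and with (open) a term for sex in the fit, 1 point per list and a wider scale for the third comparison. Medians are as fitted. The male-high kidney genes moved from -3.28 to -1.28 in the single mutant when sex was in the fit, while macrophage, matrix and tubule injury genes had the 3 highest medians of that comparison in both fits.

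Both mutants differed from wild type in many of the same genes. When sex was in the fit 361 genes were higher in both, where 33.4 would be shared by independent calls, and 1115 were lower in both against 253. None were called in opposite directions. The expected counts leave out that the comparisons share the wild type arrays and the estimate of sex. The balance of shared calls followed the scaling, with 666 higher and 658 lower in both after cyclic loess. Without single mutant 2 no gene could be called in both, since 0 were called between the single mutant and wild type. The single mutants left were all female and wild type was all male, so this does not show whether the mutants agree. Without wild type 2 the shared calls were 24 higher and 24 lower. Across genes, which are not independent replicates, the differences had a correlation of 0.957, against 0.715 in simulated groups that share their wild type arrays. Their covariance was 0.413 against 0.0371 in the simulation. As planned, Nupr1 and Msrb1 were called in both, and the covariance was 0.239 against 0.0413. Part of the excess of shared calls may come from the shared wild type arrays. In each simulation the noise was independent between genes and held no sex difference. Each mutant group held 2 females and wild type 0, so in the planned fit sex alone can make both differences move together. The simulation does not separate this from an effect shared by the mutants. The difference of the single mutant from wild type and the difference between the mutants had a correlation of -0.11 across genes, against -0.45 in simulated groups that share the single mutant arrays. Their covariance was -0.0104 against -0.0278. No gene could be called in both, since 0 were called between the mutants. With the sex term the covariance was -0.0132 against -0.0148.

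Among the mutants, sex separated more genes than genotype did. In the fit with the sex term 587 genes were higher and 141 lower in females, and 2134 had an unadjusted p under 0.05. Slc7a12, an amino acid transporter, was higher in females by 5.61, Cyp4a14, a fatty acid hydroxylase, by 5.28 and Xist by 4.78. Cyp2j13 was lower by -4.78, Slc7a13 by -4.40, Ugt2b37 by -4.10 and the organic anion transporter Slco1a1 by -3.87. Of 9 male-high kidney genes 6 were lower in females, and so were 7 when adjusted over the list alone. The same contrast held genes of injury, with lower medians in females relative to the median of all genes for tubule injury at -0.80, macrophages at -0.75 and matrix at -0.72, and a higher one for proximal tubule genes at 0.75. Camera called these 4 lists, and with an estimated correlation none passed. This contrast rests on 2 male and 4 female mutants, so sex was not separated from the injury of those 2 males. No female wild type mouse was measured, so these values describe mutant mice.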

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

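The test for an effect of sex on the second knockout was chosen after the sexes had been seen. So were the tests of male-high genes by sex and of 1 unusual male library. The test of unnamed and several-gene probe sets, and the fit with the sex term that the neighbours of the osteopontin gene were tested in, were added after the data were seen. What the tests of array scale, of tubule share and of these neighbours would show was written before their results were seen. Groups of 2 or 3 mice were not tested for single arrays far from the others.

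Camera at its preset correlation called 13 gene lists for the interaction of genotype and sex, and with an estimated correlation none passed (smallest adjusted p = 0.255). The male arm is 1 array per mutant, which is assumed to vary like the wild type and female arrays that supply the spread, so a difference between the sexes is not established. The median effect in females minus that in males was 1.72 for macrophage and monocyte genes, 1.47 for fibroblast, pericyte and smooth muscle genes, 1.46 for MHC class II and 1.36 for fibrillar collagen and matrix. It was 0.53 for tubule injury, 0.50 for basement membrane, 0.45 for the interferon response and 0.36 for endothelium. It was negative for proximal tubule transporters and markers at -0.85, oxidative phosphorylation at -0.55, cholesterol synthesis and uptake at -0.46, fatty acid oxidation and peroxisome at -0.25 and glycolysis and gluconeogenesis at -0.19. For single genes 0 of 7145 passed in limma, with 3 residual degrees of freedom, a smallest adjusted p of 0.0518 and 913 unadjusted p values under 0.05.

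Macrophage genes had a median of 1.06 in females, where 12 of 12 were higher in the double mutant, and of -0.61 in males, where 1 of 12 was. A difference in array scale is argued against by the arrays as deposited, whose 99th percentiles lay between 10.49 and 10.78. Quantile normalization could change little on such arrays, and the difference between the sexes was 1.68 after it. A lower share of tubule cells in female double mutants would raise other cell types alike. The macrophage median exceeded the endothelium median by 0.925 (bootstrap interval over genes 0.793 to 1.08). That interval holds no spread between mice, of which there were 2 females per mutant. Female single mutants had macrophage list means of 7.34 and 7.33, and female double mutants 8.24 and 8.43. Their endothelium means were 8.39 and 8.52 against 8.68 and 8.49. With 1 male library per mutant, an unusual male library and an effect of sex cannot be told apart. A sex-dependent effect of osteopontin on macrophages and matrix stays open as a hypothesis, as does a chance difference in disease stage between the 2 male mutants.

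Male-high kidney genes were lower in both mutants than in wild type, by a mean of -2.63 and -2.51. The unequal sex of the groups may account for part of this, since with male arrays alone the differences shrank by at least 1.52, to -1.11 and -0.81. Whether sex accounts for all of it cannot be told apart from an added effect of the mutation, with 1 male library per mutant. The lowest wild type array lay 0.521 above the highest male mutant array, less than the 0.58 between the wild type arrays. A difference in array scale is argued against by the arrays as deposited, whose medians lay between 5.18 and 5.25 and whose 99th percentiles lay between 10.49 and 10.78. Quantile normalization could change little on such arrays, and the smaller of the differences was -2.44 after it. Loss of male-type tubule expression in diseased kidneys stays open as a hypothesis, resting on 2 male mutants.

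Of 33 tested genes among the 50 on either side of the osteopontin gene, 5 had an unadjusted p under 0.05 between the mutants in the fit with the sex term. This was more than in 98.6 percent of 6280 windows of as many genes, whose median was 1. The genes were Plac8 at 0.65, Fras1 at -0.36, Lrrc8b at -0.44, Coq2 at -0.35 and Wdfy3 at -0.27, and none passed over all genes. Strain variants or passenger alleles carried along with the targeted gene may account for such differences. An effect of lost osteopontin on its neighbours stays open and was not tested.

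Among probe sets left out of the comparisons because they name no gene or several, 1158 passed the filter and were tested together with the named genes. Probe set 17346528, which names no gene, was higher than wild type by 3.76 in the single mutant (SE 0.39, adjusted p = 0.0367 in limma) and by 4.16 in the double mutant (adjusted p = 0.0196). Probe set 17432967, which also names no gene, was lower than wild type by -1.77 in the double mutant (SE 0.20, adjusted p = 0.033). Both were seen in 3 of 3 arrays of each group named.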

How the results depend on the processing

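The alternatives that add a sex term, use 1 sex, filter at the 50th percentile or on 2 or more arrays, use a floor or include unnamed and several-gene probe sets, and all alternatives of the fit with the sex term, were added after the data were seen. Filters and a floor based on plant probe sets and a test with microRNA stem-loops were planned and not run, as the array has no such probe sets. Between the mutants 0 genes were higher and 0 lower under every alternative run, with or without the sex term. As planned, the single mutant against wild type gave 2 higher and 5 lower genes with no filter, 289 and 518 with array weights, 0 and 0 with only the 2 groups, 0 and 0 with the replicate block, 522 and 1424 with the sex term, 564 and 1091 in males alone, where a lone sample is assumed to vary like wild type, and 2 higher with unnamed and several-gene probe sets included. Leaving out 1 array gave 0 to 2 higher and 0 to 3 lower. As planned, the double mutant against wild type gave 600 higher and 672 lower with array weights, 193 and 151 with only the 2 groups, 0 and 0 with the replicate block, 457 and 1271 with the sex term and 254 and 473 in males alone. Its lower genes were 7 with no filter, 1 with quantile normalization, 1 with median centring, 0 with cyclic loess, 4 with a trend and robust prior, 1 with a log2 difference of at least 1, 11 with the filter at the 50th percentile and 15 with that on 2 or more arrays. Leaving out 1 array gave 0 to 292 higher and 0 to 298 lower, the highest of both without single mutant 2. With the sex term the single mutant against wild type gave 805 higher genes with quantile normalization, 794 with median centring, 922 and 922 lower with cyclic loess, 247 and 795 with array weights and 218 and 547 with a log2 difference of at least 1. Leaving out 1 array gave 0 to 718 higher and 0 to 1429 lower, with 0 and 0 without single mutant 2. The double mutant against wild type with the sex term gave 736 and 838 with median centring, 809 and 760 with cyclic loess, 299 and 795 with only the 2 groups, 254 and 438 with a log2 difference of at least 1 and 748 higher with the filter at the 50th percentile. Leaving out 1 array gave 37 to 574 higher and 33 to 1195 lower, the lowest of both without wild type 2. Camera with an estimated correlation called 0 lists higher and 0 lower in each comparison and fit. Fry called 0 and 0 for the single mutant, 0 and 0 between the mutants in both fits and 2 and 0 for the double mutant as planned, and 10 lower lists for the double mutant with the sex term. The lower lists of the single mutant came to 8 with the sex term, 9 in males alone and 2 to 7 with 1 array left out (2 to 9 in the sex-term fit). Those between the mutants came to 1 with no filter, 1 with the replicate block, 1 with the sex term, 6 in males alone, 2 in females alone and 1 to 5 with 1 array left out. In the sex-term fit they came to 2 with no filter and 1 to 2 with 1 array left out. The higher lists between the mutants came to 5 to 10 with 1 array left out. Reversed list medians were counted where camera called the list as planned or in the alternative. Between the mutants, such medians reversed in males alone for fibrillar collagen and matrix (-0.72), macrophage (-0.61) and MHC class II genes (-0.52). Fibroblast (-0.50), endothelium (-0.23) and cytokine genes (-0.10) reversed there as well. In females alone proximal tubule (-0.18) and oxidative phosphorylation genes (-0.14) reversed. Of lists called in neither, complement (-0.52), interferon response (-0.26), osteopontin receptor (-0.16) and endoplasmic reticulum stress genes (-0.03) reversed in males alone. Cholesterol synthesis (-0.07), renin-angiotensin (-0.09), collecting duct (0.09) and basement membrane genes (0.05) did so in females alone. Medians of called lists reversed without single mutant 2 for proximal tubule (-0.29), oxidative phosphorylation (-0.16) and fatty acid oxidation genes (-0.031). Without double mutant 1 they reversed for endothelium (-0.16) and fatty acid oxidation genes (-0.023), and without double mutant 3 for male-high genes (-0.86). Their ranges with 1 array left out were -0.29 to 0.28 for proximal tubule, -0.16 to 0.15 for oxidative phosphorylation, -0.031 to 0.32 for fatty acid oxidation, -0.16 to 0.21 for endothelium and -0.86 to 1.06 for male-high genes. Double mutant 3 was its group's 1 male, so without it only females were compared with a group that held a male. Male-high genes lay at 9.63 in double mutant 3 and at 6.99 and 7.17 in double mutants 1 and 2. In the sex-term fit proximal tubule (-0.18 to 0.20) and oxidative phosphorylation (-0.14 to 0.13) reversed without single mutant 2 or double mutant 3, and endothelium (-0.11 to 0.14) without double mutant 1. The correlation of the single mutant's difference from wild type with the difference between mutants ranged from -0.43 to -0.040 with 1 array left out, and from -0.34 to 0.34 in the sex-term fit, where it reversed without double mutant 3. The cause of the other changes was not tested, except that a stricter threshold calls no more genes by construction. Leaving out arrays called fewer genes in some settings and more in others. After group means were taken off, single and double mutants of the same replicate number correlated at 0.256, -0.339 and -0.577. The last 2 pairs were read as of opposite sex, so pairing by number cannot be judged apart from sex. No raw signal was used, so the depth of dim probe sets over background is unknown.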

Other observations

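The splits of the mutant arrays were planned, and the other choices of male arrays were chosen after the result was seen. The 6 mutant arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 0 genes in limma, so all 10 gave at least as many, and the highest other called 1. That one put both male mutants on the same side, and 1533 of its genes had an unadjusted p under 0.05 against 104 in the real division. Sex and the injury of those 2 mice were not separated by it. For gene lists the real division called 8, at least as many were called in 6 of the 10, and the highest other called 18, again with both males on the same side.

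The number of genes called with the sex term was also counted with other mice taken as male, 1 in each mutant group. The real choice gave 1946 genes between the single mutant and wild type, the highest of the other choices gave 12, and 1 of the 9 choices, the real one, gave as many. Between the double mutant and wild type the real choice gave 1728 genes and the others 0 to 174, the highest 2 of them, 66 and 174, with single mutant 2 taken as male. With 9 choices a share under 0.05 cannot be reached. The sexes were read from the same arrays, and a wrong choice leaves the difference between the sexes in the spread, which can lower the calls. The counts therefore do not test the difference between the genotypes.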
